A study of Mus musculus with 2 samples.

How the data were processed

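H3K36me3 ChIP-seq was measured in 1 group, the forebrain of mouse embryos (strain B6NCrl) at embryonic day 12.5, with 2 biological replicates. Per the labels, replicate 1 pooled 120 embryos and was sequenced as 2 technical replicates, replicate 2 pooled 68 embryos with 1 technical replicate, both pools held male and female embryos, and the fragment size range was 300 to 500 bp. The embryos were pooled separately for each replicate, so the spread between replicates holds differences between pools and technical differences.

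The authors deposited 4 peak lists in the narrowPeak format on assembly mm10, per the file labels: peaks called for replicate 1, peaks called for replicate 2, peaks called on the pooled reads of both, and a list of replicated peaks derived from these 3. The deposited value of each peak is its fold enrichment over control, a ratio, as the authors' peak caller gave it. The deposited lists also hold each peak's −log10 p and −log10 q, which were used here only to rank or filter peaks within a list. The lowest −log10 p in any list was 2.01. The aligner, the peak caller, their versions and thresholds are not given in the sources used here. The control libraries were not analysed here. Tested on the files, 100% of the replicated peaks were identical to a pooled peak. Of the replicated peaks, 87.0% shared at least 50% of their own length or of the other peak's length with a peak of each replicate, and no pooled peak left out of the replicated list did. The rule that admitted the rest is not given in the sources used here, so a replicated peak need not be covered by a peak in both replicates. Neighbouring peaks along a gene are often separated by short gaps, so the percent covered depends on how the caller split broad enrichment.

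The depth of the libraries is unknown, since the lists hold no read counts. No interval that needs it was computed. A gene without a peak had no enrichment past the authors' threshold at that depth, which does not show that the mark was absent. Whether reads could be placed uniquely in genes with near-identical copies was not examined.

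Gene models were taken from GENCODE M21, made on GRCm38, the assembly that mm10 names, and sequence from the GRCm38 reference. No peak reached past the end of a chromosome. The analysis kept peaks on 19 autosomes, X and Y. The replicated list had 18 peaks on other scaffolds, which were left out of the comparisons. Coordinates are 1-based on mm10. Covered bases, overlaps and tests were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

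For each of 21221 protein-coding genes of at least 1 kb, the percent of the gene body (annotated start to end) covered by peaks was computed. At least 20% covered counted as marked. The replicated peaks were the main list, and each replicate's own list gave the mean and SD. The replicated list holds the longer pooled peaks, so its coverage often exceeds that of both replicates. A peak over 2 overlapping genes counts for both. Promoters were 1 kb either side of the start of a protein-coding gene, and took precedence over exons, exons over introns, and introns over intergenic sequence. Position along the gene and exons against introns used marked genes of at least 5 kb. Domains were peaks merged over gaps of up to 5 kb. Intergenic domains were made from peaks at least 10 kb from any gene and were at least 10 kb long.

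Replicate overlap and annotation shares were set against 100 circular shifts of peaks within each chromosome, one-sided. Differences along genes were tested by 100000 sign flips of chromosome means, two-sided, because neighbouring genes are not independent. Gene lists, X-linked, single-exon and lncRNA genes were set against 10000 random lists drawn with replacement from genes in the same of 20 length bins, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. These p-values treat genes as units and describe these 2 libraries only.

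Tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule named a fixed set of marker genes, up to 3 members with the highest and 2 with the lowest coverage of each list, the 10 most covered genes of at least 5 kb, the 5 genes of at least 5 kb with the largest difference between replicates in each direction, and the 5 longest domains and intergenic domains. The settings also tried were the pooled peaks, each replicate alone, stricter −log10 q, other overlap rules, equal numbers of peaks, marked calls at 10% and 40%, genes of at least 10 kb, leaving out overlapping genes, mean fold over the gene body, circular shifts or the mean for the lists, inner exons only, and gaps of 1 kb and 10 kb. Chosen after the data were seen were the mean fold that counts as marked (0.680), the share of marked members, a rotation of length-ranked coverage along the gene order, means for the X-linked, single-exon and lncRNA comparisons, and the single-exon comparison without receptor genes. A further 17 gene groups were also listed after the data were seen. The random seed was 1.

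The statistics were tested on simulated data. Covered bases of 699 genes equalled a base-by-base count in 100% of cases. For the lists, only the mean coverage was simulated, with fewer random lists. With coverage shuffled within length bins over 21221 genes, 5% of lists of 30 genes were called at 0.05. With members raised by 20 percentage points, 100% were called above random lists, and with 10 points 55.5%. The median and the share of marked members, on which the list calls rest, were not simulated, nor were lists with lowered coverage. The sign-flip test called 7% of unchanged data sets and 97% of those raised by 3 percentage points over 6875 genes. With 59.9% of peaks kept in place, the overlap found was 60.7%.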

Results

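Trimethylation of lysine 36 of histone H3 (H3K36me3), a mark known from the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse forebrain at embryonic day 12.5. At this stage the forebrain holds dividing neural progenitors and the first neurons. The series held 1 group of 2 biological replicates. Replicate 1 was a pool of 120 embryos with 2 technical replicates, and replicate 2 was a pool of 68 embryos with 1 technical replicate, each of both sexes. The deposited data were a peak list for each replicate, a list called on the pooled reads of both, and a list of replicated peaks. Read totals were not given in the sources used here, so the depth behind each list is unknown. Replicate 1 had 193146 peaks with a median length of 327 bp, and replicate 2 had 177778 peaks with a median length of 350 bp. The replicated list had 109309 peaks with a median length of 667 bp that covered 117 Mb, or 4.43% of the known bases of the chromosomes. The median fold enrichment over control was 3.13 in replicate 1 and 3.15 in replicate 2. Per gene, the measure was the percent of the gene body covered by peaks, and a gene with at least 20% covered was called marked. For single genes the coverage by replicated peaks is followed by the mean ± SD of both replicates' own lists, each with n = 2, or by both values. Among the genes named below, Gigyf1, 1700109H08Rik, Pla2g4b, Phykpl, Prss53, F2rl2, Fastk, Gapdh, Sf3b3, Tead2, Foxg1, Nsg1, Elavl3, Tubb3, Cnp, Cx3cr1, Csf1r, Nnat, Ttc19, Ncor1, Usp34 and Ahsa2 overlap another protein-coding gene, so a peak there cannot be given to either gene.

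How far did the replicates share their peaks and genes? The same genes carried the mark in both: 6433 protein-coding genes were marked in replicate 1, 6304 in replicate 2 and 6091 in both. Across 21221 protein-coding genes of at least 1 kb, coverage in the replicates had a Pearson correlation of 0.986 and a Spearman correlation of 0.962, where genes are not independent replicates. Only 3 genes of at least 5 kb had at least 20% covered in 1 replicate and under 5% in the other: Adam15 and F2rl2 in replicate 1 and Stac3 in replicate 2. The largest differences among genes of at least 5 kb were Prelid3b, with 52.7% covered in replicate 1 and 21.3% in replicate 2, and Fastk, with 39.5% in replicate 1 and 75.6% in replicate 2. The X-linked genes Fam50a and Emd were also among the 5 genes that leaned most to replicate 1, and Sox11, a transcription factor of young neurons, was among the 5 that leaned most to replicate 2. Single peaks were shared less completely than genes. Of the replicate 1 peaks, 58.4% had at least 50% of their length covered by replicate 2 peaks, against a mean of 4.22% in 100 circular shifts (permutation p = 0.0099, the smallest that 100 shifts can give, one-sided). In the other direction the share was 61.5%, against 4.26% in the shifts. The Jaccard index of covered bases was 54.2%. Shared peaks of replicate 1 were longer, with a median of 441 bp against 244 bp for the others, and had a higher median fold of 3.52 against 2.87.

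Where in the genome did the mark lie? It lay in genes. Introns held 76.2% of the bases covered by replicated peaks, exons 18.8%, promoters 0.436% and intergenic sequence 4.59%. Relative to the share of the assembly in each class, exons were covered 5.31-fold and introns 1.89-fold, while the ratio was 0.288 for promoters and 0.0841 for intergenic sequence. Each share lay outside the range of 100 circular shifts of the same peaks (permutation p = 0.0099 for each class, the smallest possible, one-sided). In the shifts exons took at most 4.07%, and promoters took at least 1.49%.

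How was the mark distributed along a gene? It was sparse at the 5′ end and higher on the 3′ side. The bodies of 6185 marked protein-coding genes of at least 5 kb were divided into 10 equal parts. On average the first part was covered over 6.76%, the fifth over 56.3% and the ninth over 72.0%, and coverage was lower again in the last part, at 67.6% (60.3% in replicate 1 and 60.9% in replicate 2). The 5 parts on the 3′ side were covered over 67.5% and the 5 on the 5′ side over 35.2%. This difference was 31.9 ± 2.95 percentage points (mean ± SD over chromosomes) and had the same sign on 20 of 20 chromosomes with marked genes (sign-flip permutation p = 1e-05, the smallest possible, two-sided). The 3′ side was higher in 89.1% of these genes. The difference was 45.6 percentage points in genes of 5 to 10 kb and 25.1 in genes of at least 100 kb. Exons were covered more than introns. In 6174 multi-exon marked genes the means were 65.9% for exons and 48.6% for introns, a difference of 17.3 ± 1.71 percentage points over chromosomes (sign-flip permutation p = 1e-05, two-sided, same sign on 20 of 20 chromosomes). Without the first and last exon of each gene, the difference was 13.6 percentage points over 5870 genes. Exons and introns were not matched on position along the gene, so the rise toward the 3′ side may contribute to the difference.

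**Figure D1:**
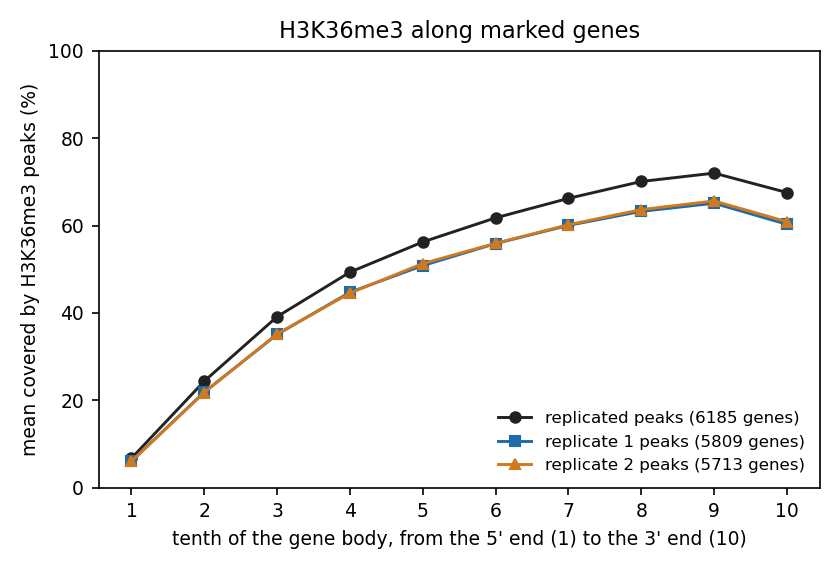
Mean percent covered of each of 10 equal parts of the gene body by H3K36me3 peaks (vertical axis), from the 5′ end to the 3′ end (horizontal axis), over marked protein-coding genes of at least 5 kb, for the replicated peaks and for each replicate's own peaks. Coverage by replicated peaks rose from 6.76% in the first part to 72.0% in the ninth and was 67.6% in the last, and both replicates followed the same course.

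Which genes carried the mark? With replicated peaks, 6875 of 21221 protein-coding genes were marked (32.4%), and 10698 had no replicated peak. The share of marked genes peaked at intermediate gene length, at 44.6% in genes of 12.9 to 18.5 kb, and was 15.6% in genes of up to 3.53 kb and 9.75% in genes of at least 112.7 kb. The call is a share of gene length, so it asks for more covered bases in a longer gene. A replicated peak lay in 58.6% of genes of at least 112.7 kb and in 56.4% of those of 12.9 to 18.5 kb. The mean covered length was 10.7 kb in the former and 4.05 kb in the latter. Among genes of at least 5 kb, the most covered was Gigyf1 (chromosome 5, 137518548 to 137527935), with 96.5% in replicate 1 and 94.6% in replicate 2, followed by genes that included Sf3a1 with 94.1% (89.3% ± 0.0828), Ints1 with 93.7% (85.9% ± 0.475) and Trrap with 93.5% (89.6% ± 0.870). Sf3a1 is a subunit of the splicing factor SF3A, Ints1 of the Integrator complex, and Trrap of histone acetyltransferase complexes. The other 6 of the 10 most covered were 1700109H08Rik, Pla2g4b, Phykpl, Prss53, Gpi1 and Rnf40. Of these 10 genes, 5 overlap another protein-coding gene. Genes with constant use in most cells included Eef2, translation elongation factor 2, at 86.0% (84.3% ± 3.02), Actb at 74.0% (65.5% ± 1.57), Polr2a, the largest subunit of RNA polymerase II, at 57.7% (57.3% ± 0.482) and Gapdh at 41.1% (37.4% ± 1.64).

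To ask which gene groups stood apart, 26 lists fixed before the data were examined were set against 10000 random lists of genes matched on length. The median coverage of 10 lists lay above the random lists after Benjamini-Hochberg adjustment over the lists, and no list lay below. Because the median of many lists was 0, the share of marked members was also tested, an alternative chosen after the data were seen. By that measure 10 lists lay above and 13 below. The p-values say only whether a list stood apart from genes of the same length in these 2 libraries.

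Of the DNA replication and cell cycle genes, 41 of 42 were marked, with a median coverage of 69.9% (adjusted permutation p = 0.00065, where the smallest unadjusted value possible was 0.0002). Top2a, the topoisomerase of dividing cells, was covered over 91.7% (84.7% ± 1.37), Mcm2, a subunit of the replicative helicase, over 91.3% (84.5% ± 2.09) and Aurka, a mitotic kinase, over 88.1% (79.2% ± 1.43). The member below the call was X-linked Pola1, at 1.98% (1.82% ± 0.462). The spliceosome list had 79 of 84 members marked and a median of 64.0%, led by Sf3a1 and Sf3b3 at 92.4% (88.4% ± 0.451). The translation factors had 51 of 59 marked (median 58.6%), the proteasome 39 of 48 and the cytosolic ribosomal proteins 68 of 81 (median 54.4%). Oxidative phosphorylation genes had 65 of 83 marked (median 41.2%). Each of these lists had the same adjusted permutation p of 0.00065. Members without a replicated peak numbered 4 in the ribosomal protein list, 6 in the proteasome, 3 in the spliceosome, 2 in the translation factors and 9 in oxidative phosphorylation. They included Rpl10l, Rpl39l and Psma8, which are known for expression in testis, and also Psmb10, Sf3b5, Hnrnph2, Eif3j2, Eef1a2, Atp5k and Atp5s. The H3K36 methylation enzymes and readers had 20 of 26 members marked and a median of 54.6% (adjusted permutation p = 0.00065). Kdm4a, an H3K36 demethylase, was covered over 91.7% (88.7% ± 0.753), the methyltransferases Nsd1 over 67.4% (60.1% ± 0.448) and Setd2, which writes H3K36me3, over 52.9% (44.0% ± 2.75).

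Of the forebrain progenitor list, 18 of 35 members were marked and the median was 24.1% (adjusted permutation p = 0.00578). With the peaks of a single replicate the median was 17.5% in replicate 1 (adjusted permutation p = 0.0116) and 15.4% in replicate 2 (0.0179). Msi1, an RNA-binding protein of neural stem cells, was covered over 86.4% (79.1% ± 2.37), Tead2 over 82.9% (78.2% ± 1.62), the intermediate filament genes Vim over 60.8% (54.8% ± 2.28) and Nes over 51.2% (49.2% ± 5.33), Lhx2 over 38.9% (33.2% ± 3.42), Foxg1 over 28.0% (23.9% in replicate 1 and 12.1% in replicate 2) and Pax6 over 24.1% (19.6% ± 1.21). Short genes varied between replicates: Sox2, of 2.06 kb, was covered over 32.4% by replicated peaks, with 0% in replicate 1 and 18.4% in replicate 2, so neither replicate alone marked it. Hes5, of 1.45 kb, was covered over 24.5%, with 34.9% in replicate 1 and 0% in replicate 2. Replicated peaks have the extent of the pooled peaks, on which both calls rest. The list no longer passed the test in genes of at least 10 kb (adjusted permutation p = 0.111) or by the share of members covered over at least 40%, which was 20% in the list and in random lists (adjusted permutation p = 1). The share of marked members passed with replicate 1 peaks alone (adjusted permutation p = 0.00867) and not with replicate 2 peaks alone (adjusted permutation p = 0.207). The pan-neuronal list had 14 of 36 members marked and a median of 10.2% (adjusted permutation p = 0.0328). Nsg1 was covered over 88.6% (83.0% ± 0.504), Tagln3 over 81.9% (67.6% ± 2.82), Elavl3 over 49.5% (39.7% ± 3.82) and Tubb3, neuronal tubulin, over 46.5% (42.3% ± 6.12). Map2 was at 12.1% (11.5% and 10.4%), Stmn2 at 11.5% (9.48% ± 0.563) and X-linked Dcx at 0.494% (0.711% ± 0.0411). This call was lost with the stricter peaks of −log10 q of at least 5 (adjusted permutation p = 0.0551), in genes of at least 10 kb (0.0566) and with the share of marked members (0.0559).

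The pallial lineage list, with genes of the developing cortex, had 1 of 20 members marked (adjusted permutation p = 0.0437 for the share of marked members). With the peaks of a single replicate the list did not pass (adjusted permutation p = 0.0692 in replicate 1 and 0.0815 in replicate 2), nor did it with the call at 10% (0.0518) or 40% (0.310). The marked member was Dmrta2 at 42.3% (25.5% ± 4.24). Neurog2 and Tbr1 had no peak in either replicate, and Eomes had no replicated peak. The subpallial list, with genes of the ventral forebrain, had 1 of 22 members marked (adjusted permutation p = 0.0158), Olig2 at 20.9% (7.39% ± 10.4). It did not pass with the rotation along the gene order, which keeps neighbouring genes together (adjusted permutation p = 0.185). Dlx2 was at 18.5% (21.2% in replicate 1 and 5.62% in replicate 2) and Gad1 at 2.80% (7.75% ± 0.558), and Dlx1, Gsx2 and Nkx2-1 had no peak in either replicate.

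Genes of mature neurons and of other cell types were rarely marked. The mature neuron and synapse list had 1 of 26 members marked (adjusted permutation p = 0.0040 for the share of marked members), Dlg4 at 39.2% (35.5% ± 2.05). The astrocyte and oligodendrocyte list had 1 of 16 (adjusted permutation p = 0.0138), Cnp at 78.9% (76.4% ± 1.21), whose overlapping gene is Dnajc7. With the call at 40% the latter list did not pass (adjusted permutation p = 0.128). No member was marked in the lists of vascular and meningeal (21 members), erythroid (15), liver, gut and pancreas (24), cardiac and skeletal muscle (20), germline (17), midbrain and hindbrain patterning (22) or Hox genes (39), each below random lists with adjusted permutation p from 0.00052 to 0.0107. With the call at 40% the erythroid list (adjusted permutation p = 0.0694) and the midbrain and hindbrain list (0.0662) did not pass. None of 39 Hox genes had a replicated peak, and of 1302 olfactory and vomeronasal receptor genes 1 had. The microglia and leukocyte list had 1 of 17 members marked and did not pass the test (adjusted permutation p = 0.0511). Its marked member was Cd68, of 1.94 kb, at 100% in both replicates, while Cx3cr1 was at 17.6% (15.3% ± 0.165) and Csf1r at 9.74% (9.33% ± 0.0112). Peaks thus reached both ends of Cd68, and whether they belong to a neighbouring gene was not examined. Imprinted genes did not stand apart from length-matched genes, with 10 of 35 marked, though their median did against circular shifts (adjusted permutation p = 0.0468). They were led by Nnat at 86.5% (82.1% ± 6.04), which lies within the transcript of Blcap. Of the clustered protocadherins 21 of 57 were marked (adjusted permutation p = 0.0138), but these genes share exons and are not independent. The list did not pass with the rotation along the gene order (adjusted permutation p = 0.515) or with the call at 10% (0.259). None of the 19 replication-dependent histone genes of at least 1 kb was marked (adjusted permutation p = 0.0472, and 0.0692 and 0.0839 with the peaks of replicates 1 and 2 alone). This list did not pass with the rotation (adjusted permutation p = 0.247) or with the call at 40% (0.213).

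**Figure D2:**
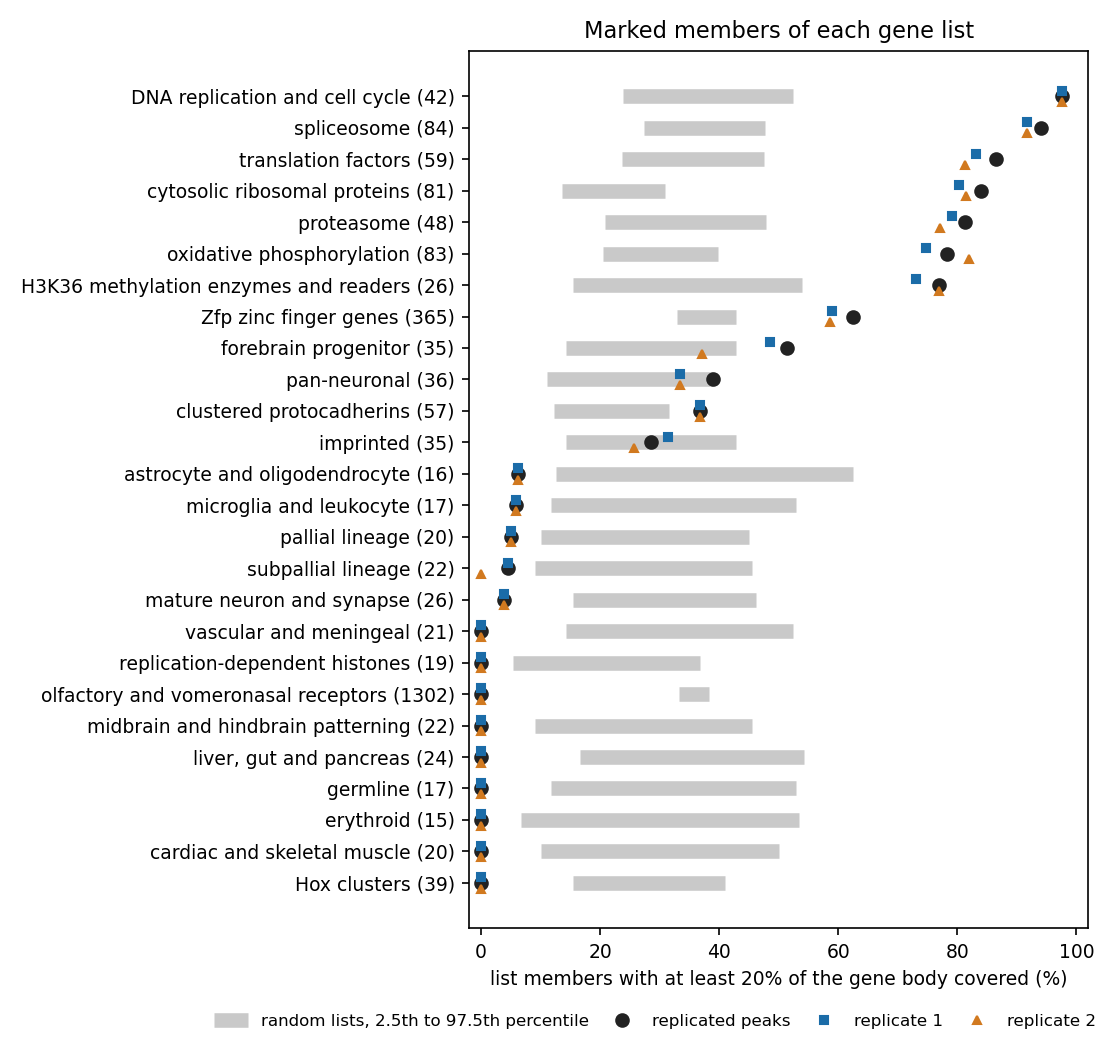
Percent of the members of each gene list with at least 20% of the gene body covered (horizontal axis), for replicated peaks and each replicate's own peaks, with the number of members in parentheses. Grey bars span 10000 length-matched random lists without the 2.5% at either end; the DNA replication and cell cycle list lay highest, at 97.6%, and 9 lists lay at 0%.

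Zinc finger genes named Zfp with a number, a large family of DNA-binding proteins, held many of the strongest peaks. Of 365 such genes 228 were marked, with a median coverage of 31.7% (adjusted permutation p = 0.00065). Among the 50 replicated peaks with the highest −log10 p, 26 overlapped such a gene, as did 23 of the 50 strongest peaks of replicate 1 and 24 of replicate 2. The strongest replicated peak lay on chromosome 7 from 30160637 to 30164367 (mm10), with 16.6-fold enrichment, over the last exon of Zfp146 (30161269 to 30163228). The next were over the last exons of Zfp68 (chromosome 5, 138604734 to 138608815, 15.7-fold) and Zfp763 (chromosome 17, 33017654 to 33020361, 16.0-fold). The Zfp146 peak also ranked first in replicate 2 but only 5th in replicate 1. The strongest peak of replicate 1 by −log10 p lay at Mid1 on the X chromosome (169988483 to 169989567, 9.30-fold). Its fold was below the 14.9-fold of the peak ranked 2nd, and the peak there in replicate 2 ranked 25th (6.44-fold). By coverage the family was led by Zfp869 at 97.4% (96.0% ± 3.85).

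**Figure D3:**
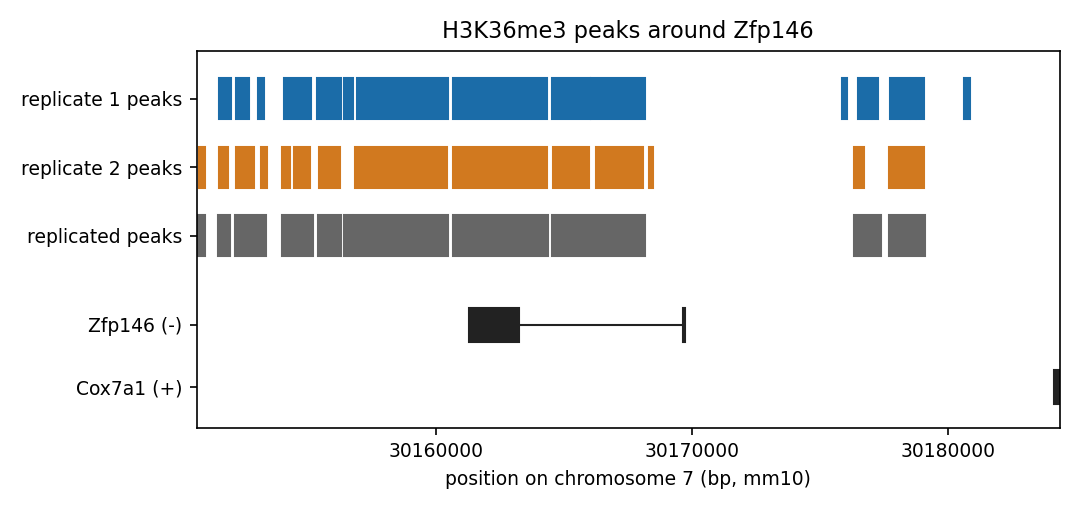
Map of chromosome 7 from 30150638 to 30184367 (mm10; horizontal axis in bp) with the peaks of each replicate, the replicated peaks, and the exons (boxes) and introns (lines) of the protein-coding genes. Zfp146 is read from right to left; its long last exon lay within the 16.6-fold peak, and peaks continued past its 3′ end.

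Did X-linked genes differ from autosomal genes? Far fewer were marked. On the X chromosome 83 of 877 genes were marked (9.46%), against 6792 of 20181 autosomal genes (33.7%). Single autosomes ranged from 24.8% to 42.4%. The replicates alone gave 7.98% and 7.41% for the X chromosome. The median coverage was 0 for X-linked genes and in length-matched random lists of autosomal genes, so the planned test of medians could not tell them apart (permutation p = 1). The mean, chosen after the data were seen, was 4.86% against a random median of 17.3% (permutation p = 0.0002, the smallest possible, two-sided). None of 163 Y-linked genes was marked, and the Y chromosome held 11 replicated peaks in all. Whether reads could be placed uniquely there was not examined, and only the male embryos of each pool carry a Y chromosome. The count therefore does not show that the mark was absent.

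**Figure D4:**
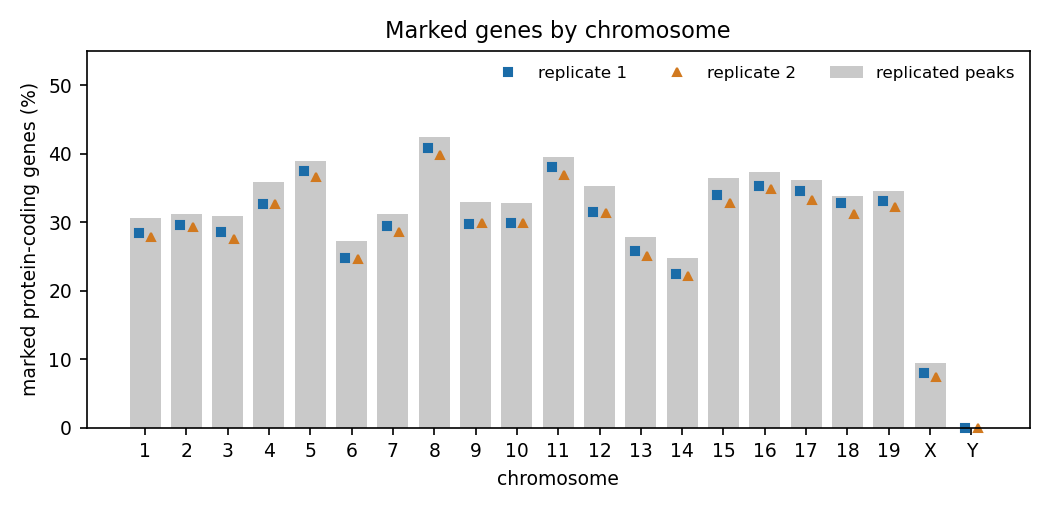
Percent of protein-coding genes of at least 1 kb that were marked on each chromosome (vertical axis), with replicated peaks as bars and each replicate's own peaks as points. The X chromosome stood at 9.46%, below every autosome, of which the lowest was chromosome 14 at 24.8%.

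Genes with a single exon and noncoding genes were marked less. Of 791 single-exon protein-coding genes 8.47% were marked, and their mean coverage was 4.86%, against 9.75% in length-matched multi-exon genes (permutation p = 0.0002, two-sided; the planned medians were both 0, permutation p = 1). Of 5580 long noncoding RNA (lncRNA) genes that overlap no protein-coding gene, 78 were marked, with a mean coverage of 0.802% against 16.0% in length-matched protein-coding genes (permutation p = 0.0002; medians both 0, permutation p = 1). The marked lncRNA genes of at least 5 kb included Snhg17, a small nucleolar RNA host gene, at 73.9% (72.4% in replicate 1 and 75.3% in replicate 2), and Mir9-3hg, the host of a neural microRNA, at 58.2% (55.6% and 46.1%). These 2 were chosen after their values were seen. Of the pseudogenes without overlap, 0.455% of 1759 processed and 0.266% of 1126 unprocessed ones were marked. The unprocessed share was 0.0888% with replicate 1 and 0.178% with replicate 2 alone. Whether reads could be placed uniquely in pseudogenes was not examined, so these low shares do not show that the mark was absent there.

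Merged over gaps of up to 5 kb, the replicated peaks formed 16391 domains with a median length of 5.11 kb, of which 611 were at least 50 kb long. The median length was 3.003 kb with the peaks of replicate 1 alone and 3.71 kb with those of replicate 2 alone, and 1116 domains of pooled peaks were at least 50 kb long. The extent also depended on the gap: with gaps of 1 kb, 46 were that long and the longest was 102.6 kb, and with gaps of 10 kb, 1253 were that long. The longest spanned 234 kb on chromosome 12 (75879051 to 76113509) over Syne2, which encodes a giant nuclear envelope protein, with 181 kb covered (157 kb in replicate 1 and 158 kb in replicate 2). The next lay over Ttc19 and Ncor1 (chromosome 11, 155 kb), Vps13d (chromosome 4, 154 kb), Herc2 (chromosome 7, 152 kb), and Usp34 and Ahsa2 (chromosome 11, 152 kb). Of the replicated peaks, 125 (0.114%) lay at least 10 kb from any annotated gene, as did 875 peaks of replicate 1 (0.453%), 551 of replicate 2 (0.310%) and 793 pooled peaks (0.407%). The replicated ones formed 1 domain of at least 10 kb, against 3 with the peaks of replicate 1 alone, 4 with those of replicate 2 alone and 5 with pooled peaks. It lay on chromosome 4 (91210950 to 91234010), 16.8 kb downstream of Elavl2, a neuronal RNA-binding protein gene. Of its 23.1 kb, replicated peaks covered 10.4 kb, replicate 1 peaks 8.52 kb and replicate 2 peaks 7.39 kb.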

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

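Of the replicated peaks, 18 lay on unplaced or unlocalized scaffolds, outside the chromosomes used in the comparisons, so no comparison used them. Of these, 8 lay on a single unplaced scaffold. Replicate 1 had 44 such peaks and replicate 2 had 29. The 18 peaks covered 14.3 kb, and the highest fold among them was 9.82. The cause was not tested.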

How the results depend on the processing

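The share of marked members, the rotation along the gene order, the means for X-linked, single-exon and lncRNA genes, and the single-exon comparison without receptors were chosen after the data were seen. Of 118 alternatives to the tested and counted results, 96 kept their direction and side of the threshold or stayed within 1.5 times the count. The direction of the replicate overlap, annotation shares, position along the gene and exons against introns held under every alternative run, and no result reversed. Of 335 alternatives for single lists, 268 kept the call, 62 gained it and 5 lost it. Of 644 for single genes, 397 moved by less than 1 SD of the replicates.

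The count of marked genes fell from 6875 to 4565 with the call at 40%. Lists below random lists, 0 by the median, were 1 in genes of at least 10 kb, 13 by the mean, 13 by the share of marked members, 12 and 8 with that share at 10% and 40%, and 11 by rotation. The median cannot fall below random lists whose median is 0. X-linked genes kept a median of 0 and passed the test with pooled peaks (permutation p = 0.0162), without replicate 2 (permutation p = 0.040) and in genes of at least 10 kb (permutation p = 0.0002). They did not pass without replicate 1 (permutation p = 0.310). Nor did they pass with −log10 q of at least 5, without overlapping genes or by mean fold over the gene body, where the random median was also 0. By the mean, X-linked genes (4.86%), single-exon genes (4.86%, or 5.28% without receptors) and lncRNA genes (0.802%) passed. Genes that differ between replicates numbered 9 at 10% against 0% and 0 at 40% against under 10%. Intergenic domains numbered 5 with pooled peaks, 3 to 4 with a single replicate's peaks, 0 with gaps of 1 kb and 4 with gaps of 10 kb. Domains numbered 38034 with gaps of 1 kb. A cause was tested for the intergenic domains and for the genes that differ, and neither test, given below, decided it. Unknown depth limits what an uncovered gene shows.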

Other observations

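A further 17 gene groups, and the tests on X-linked genes, single-exon genes and last-exon length, were chosen after the patterns they concern were seen. The groups were tested by the share of marked members. All 20 cytosolic aminoacyl-tRNA synthetase genes were marked, led by Rars at 87.6% covered. The nuclear pore genes had 22 of 24 members marked, the mitochondrial ribosomal proteins 60 of 75, the Mediator and Integrator subunits 35 of 44, and the histone demethylases, acetyltransferases and deacetylases (Kdm, Kat and Hdac genes) 26 of 36. The kinesins, motor proteins of mitosis and axonal transport, had 26 of 38 marked, led by the mitotic Kif2c at 87.7% and Kif23 at 83.7%. With the peaks of replicates 1 and 2 alone, these counts were 20 and 19, 22 and 22, 60 and 57, 33 and 33, 24 and 22, and 24 and 23. Each of these 6 groups lay above length-matched random lists (adjusted permutation p = 0.00038). No voltage-gated ion channel gene of 52, no keratin gene of 49 and no defensin gene of 40 was marked (adjusted permutation p = 0.00038, 0.00038 and 0.0010). Of 44 collagen genes 1 was, Col2a1 at 65.2%, and of 43 glutamate and GABA receptor genes 2 were, Grik5 at 82.9% and Grin3b, which overlaps another gene, at 42.1% (adjusted permutation p = 0.00038 and 0.0022). Wnt and Frizzled genes had 4 of 29 marked, below random lists (adjusted permutation p = 0.0170), with Wnt7a at 41.1%. With replicates 1 and 2 alone, 3 and 2 of them were marked. Axon guidance genes did not stand apart, with 22 of 67 marked (adjusted permutation p = 0.275), among them Plxnb1 at 84.5% and Ephb4, which overlaps another gene, at 76.9%. The classical cadherins had 2 of 23 marked (0.259) and the Sox genes 6 of 19 (0.442), as adjusted permutation p. The intraflagellar transport genes had 9 of 14 marked, which did not pass by that share (adjusted permutation p = 0.0653). Their median of 38.3% lay above the random median of 5.49% (adjusted permutation p = 0.0325). The Hnf and Fox genes had 6 of 46 marked, below random lists (adjusted permutation p = 0.0358), and 5 and 4 with replicates 1 and 2 alone. In single replicates, 18 and 15 axon guidance, 2 and 1 cadherin, 4 and 4 Sox, and 8 and 8 intraflagellar transport genes were marked. The counts of the channel, keratin, defensin, collagen and receptor groups were the same in both. By the median, the 6 groups above random lists stayed above (adjusted permutation p = 0.00057), and no group passed the test below; the groups below by the share had medians of 0.

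The low coverage of X-linked genes was weighed against 3 explanations. Gene content alone was argued against: among 6 broadly expressed lists, 11 X-linked members had a mean coverage of 10.2%, below the 36.5% to 63.4% of random draws of autosomal members of the same lists. These draws were matched on list and not on gene length. The name pattern of the translation factor list left out X-linked Eif2s3x, at 59.0%. Repeats and base composition as the whole cause were argued against too, since X-linked genes matched on length, masked share and GC content kept a mean of 4.86% against 12.8% to 15.7% in autosomal genes. A candidate explanation is that each cell uses 1 X chromosome while it uses both copies of an autosome: fold enrichment in marked X-linked genes was 0.773 of that in length-matched autosomal genes (bootstrap interval 0.750 to 0.812), and 3 of 5 genes known to escape X inactivation were marked, Eif2s3x at 59.0%, Kdm5c at 56.3% and Ddx3x at 51.0%, but Kdm6a had 4.61% and Pbdc1 0%. Any cause of weaker enrichment on the X chromosome would also lower the fold, which was compared only in the 83 X-linked genes that were marked, so these values do not single out this explanation, and the lower X copy number of male embryos, which would leave fewer reads to pass the peak threshold, stays open.

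Single-exon genes were covered less than multi-exon genes of the same length. Receptor families as the cause were argued against: olfactory and vomeronasal receptors made up 62 of 791 single-exon genes, and without them the mean was 5.28%, against a random median of 10.4% (permutation p = 0.0002). A biological explanation was not tested.

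Of the 3 genes covered in 1 replicate and hardly in the other, 66.7% leaned to replicate 1, and all 3 stayed when both lists were limited to the same number of peaks, which leaves a removed share of up to 70.8% (exact interval). With 3 genes, whose exact binomial interval runs from 9.43% to 99.2%, a lower effective threshold in replicate 1 cannot be told apart from other causes.

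One hypothesis concerned the zinc finger genes, in many of which the last exon holds the finger domains. The genes were chosen by name, and the place of the fingers in each was not examined. In 228 marked Zfp genes the last exon was covered more than the rest of the gene by a median of 40.6 percentage points, above the 20.5 to 29.4 of length-matched marked genes (permutation p = 0.0002). The median was 37.8 in replicate 1 and 39.8 in replicate 2. Their last exons were longer, at a median of 2.54 kb against 1.25 kb. Against genes matched on the length of the last exon, the 40.6 percentage points still lay above the 18.1 to 28.0 of random lists. This was 17.7 percentage points above the random median of 22.9. Coverage of the last exon had a median of 87.3% in Zfp genes and 82.0% in other marked genes, and the rest of the gene 43.4% and 47.2%. These medians are over all other marked genes, not matched on the length of the gene or of the last exon. Whether the larger difference comes from a higher last exon or a lower rest of the gene was not tested. The other hypothesis was that intergenic domains may come from transcription past annotated genes. The 1 domain, or 100% of domains, lay within 50 kb downstream of its nearest gene, against 28% of random placements, and a single domain does not decide it.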
